A study of Mus musculus with 48 samples.

How the data were processed

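RNA of jejunal epithelium from female C57BL/6 mice was compared on 48 two-colour Agilent arrays. Per the labels, the mice received sesame oil or 1 of 8 doses of the dioxin TCDD by gavage every 4 days for 28 days. One label also calls the gavage daily, and the interval of 4 days was taken because the other label that gives a schedule states it. Each array held the RNA of 1 treated animal and 1 vehicle animal, labelled with Cy3 and Cy5 as an Agilent manual describes, per the labels' protocols. Each of 24 such animal pairs was measured on 2 arrays with the dyes exchanged, which gives 3 pairs at each of the 8 doses. The 24 treated animals differ, but only 3 vehicle animals were used, each set against 1 treated animal at every dose.

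The deposited values are log ratios of 41085 probes on the 48 arrays. The base of the logarithm is not stated and was taken as log2, which the deposited values do not contradict. The labels name no scanner software, background correction, normalization or filter. Of the cells, 25% are empty, and the arrays hold 27341 to 33126 values with medians of -0.10 to 0.08. The files hold no intensities, so dim spots could not be removed and what they limit is unknown. The number of animal pairs, 3 per dose with 3 shared vehicle animals, limits the precision.

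The sign of the ratios is not stated either. A profile of dye effects dominates each dye orientation, and the mean profiles of the 2 orientations have a correlation of -0.59 across probes. As deposited, the 2 arrays of a pair correlated between -0.25 and 0.54 across probes, below 0 in 10 of 24 pairs. With the mean profile of each orientation removed, they correlated between 0.018 and 0.80, with a median of 0.44. Cyp1a1 was above 0 on 12 of the 12 arrays at 10 and 30 µg/kg in both orientations. The textbook TCDD-induced genes fixed for this purpose had a mean log2 ratio at 3 to 30 µg/kg of 1.12 with the treated animal in Cy5 and 0.92 with it in Cy3. The values were therefore read as treated over vehicle without turning any sign, a direction that is likely and rests on these genes.

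The table also holds a value that many probes share on the same array. On each array, 203 to 335 probes have exactly the same log ratio. On all 48 arrays this holds for 189 probes, and 76 more probes with values on every array have it on 6 to 47 arrays. Such a value cannot be a measurement of each of these genes. These probes stayed in the tests, since the gene values had been defined before the data were examined, and an alternative chosen after seeing the data leaves them out. All probes of 118 tested genes are of this kind on 6 or more arrays, and 0 of these genes were called at any dose. They are treated as not measured in the text, and 83 further genes have some such probes.

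The 2 arrays of a pair were averaged to 1 value. Probes with a value on all 48 arrays that name exactly 1 gene, 17836 of the 21105 complete probes, were averaged to 13065 genes. Probe names came from the array's annotation table, which lists 32600 probes, 32555 of them with 1 symbol. It lacks 8485 probes of the table. Gene symbols were matched by gene identifier to an annotation of assembly GRCm38.p6 for 32416 of the 32555 probes. No coordinates were used.

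Each dose was tested with limma 3.58.1 (R 4.3.3, statmod 1.5.0) by lmFit and eBayes, with 1 mean per dose in a fit of all 24 pairs and the mean log2 ratio tested against 0, two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 at a dose are called. All doses share 1 estimate of the spread, so the adjusted p of a gene is not that of its 3 pairs alone. A slope on log10 dose and the contrast of 30 and 10 µg/kg were tested in the same way. Of 33 gene lists written before the data were examined, 32 with at least 5 measured members were tested at each dose with camera at its preset correlation of 0.01, with an estimated correlation and with fry. Several list members are not in the annotation used and were not analysed here. Values are means of log2 ratios with the SD over the 3 pairs.

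Ratios of the same replicate number share a vehicle animal. After the dose means were removed, ratios with the same vehicle animal correlated with a mean of 0.28 across genes over 84 combinations, and ratios with different vehicle animals with a mean of -0.14. A block for the vehicle animal was therefore run as an alternative for every count.

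Genes are named by a rule fixed before the data were examined. It takes the 10 largest called rises and falls at 30 µg/kg with the same sign in all 3 pairs, and the 3 largest at each other dose. It adds the 4 genes with the smallest p at 30 µg/kg in each list and all measured members of the aryl hydrocarbon receptor (AHR) battery. It ends with the 5 largest called slopes each way and the 5 largest called differences each way between 30 and 10 µg/kg. Predicted and clone-named genes were skipped.

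Alternatives covered the block, single dye orientations, array centring, quantile normalization, the handling of probes, array weights, a robust prior, thresholds of 1.5-fold and 0.01, the pairs of the dose alone and leaving out each pair. Those chosen after seeing the data use probes complete at a dose, leave out probes at the shared value, or deal with a signal of exocrine pancreas genes. That signal was the pair's median over 10 enzyme genes, entered as a covariate or used to leave out pairs above 0.5. The scripts were tested on simulated data with known changes. At 30 µg/kg, 79.1%, 98.5% and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale were called, with 2 unchanged genes called and 0 wrong signs. The simulated genes varied independently, without array offset or pancreas signal, so these rates do not give the accuracy of the real calls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.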

Results

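The series asks what TCDD, a persistent ligand of AHR, does to gene expression in the jejunal epithelium. Its title names lipid metabolism and immune cell populations. The data are log2 ratios of treated over vehicle animals for 13065 genes in 24 animal pairs, 3 at each of 8 doses from 0.01 to 30 µg/kg. The 2 dye-swapped arrays of a pair count as 1 replicate (n = 3 pairs per dose throughout). The 3 vehicle animals are shared by all doses, so results at different doses are not independent. The log base and the sign of the ratios are not stated in the labels and were taken as 2 and treated over vehicle.

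At 30 µg/kg, 561 genes were called, 114 higher and 447 lower. Pou3f1, a POU-domain transcription factor, rose most, by a log2 ratio of 4.36 ± 0.02 (SD, n = 3; limma adjusted p 9.8e-13). The muscle actin gene Acta1 rose by 3.31 ± 0.29 (adjusted p 7.9e-07) and Cyp1a1 by 3.02 ± 0.38 (adjusted p 0.00038). Bco1, which cleaves beta-carotene, rose by 2.31 ± 1.33 (adjusted p 0.0176) and Tmigd1 by 1.98 ± 0.86 (adjusted p 0.0124). The other largest rises were those of Olfr114 (1.73 ± 0.62), Wdr11 (1.71 ± 0.30), Gabbr1 (1.54 ± 0.05), Tiparp (1.41 ± 0.26) and Rab33a (1.22 ± 0.18). The rise of Gabbr1 is not shared by its 3 probes: their median was at 0.05 (adjusted p 0.832) and the weakest at -0.02 (0.970). The immunoglobulin joining chain gene Jchain fell most, with a log2 ratio of -1.74 ± 0.66 (adjusted p 0.0139), followed by the alcohol dehydrogenase gene Adh4 at -1.58 ± 0.49 (adjusted p 0.0033). Apol10a (-1.20 ± 0.78), Ighv1-33 (-1.17 ± 0.79), Dnase1 (-1.10 ± 0.25), Dnajb3 (-1.06 ± 0.47) and Ighv1-17 (-1.01 ± 0.38) also fell. So did Plscr1 (-0.96 ± 0.22), Wdfy4 (-0.94 ± 0.43) and the malic enzyme gene Me1 (-0.93 ± 0.48). After centring, which moved each mean up by 0.06, the calls of Apol10a, Ighv1-33, Dnajb3, Ighv1-17, Plscr1, Wdfy4 and Me1 ended (adjusted p 0.0501 to 0.0747).

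The split at 30 µg/kg depends on the level of the arrays. The median of all genes at this dose was -0.05, and 20.3% of the called genes were higher. After each array was centred on its median, 279 genes were called, 142 higher and 137 lower, of which 249 were among the 561. At least 1.5-fold changes were called for 102 genes, 47 higher and 55 lower. Of the 57 genes that the naming rule gives and that were called at 30 µg/kg, 18 kept their calls when any 1 of the 3 pairs was left out. These were Pou3f1, Acta1, Cyp1a1, Olfr114, Wdr11, Gabbr1, Tiparp, Rab33a, Adh4, Dnase1, Taf15, Txnrd3, Cyp2s1, Ahr, Thy1, Aldh1a1, St6gal1 and Olfr1182. Without replicate 1, 23 of the 57 stayed called, without replicate 2, 34, and without replicate 3, 32. After centring, 32 of the 57 stayed called. Of 14 among the 57 with more than 1 probe, 6 were called by their weakest probe, and Gabbr1, Ighv1-33, Me1, Slc27a2, Stard4, Tnfrsf13b, Itgax and St6gal1 were not. The total of called genes without each replicate was 175, 404 and 248. Replicates 1 and 3 at this dose carry a signal of pancreas genes, and 71 genes were called with both left out.

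**Figure D1:**
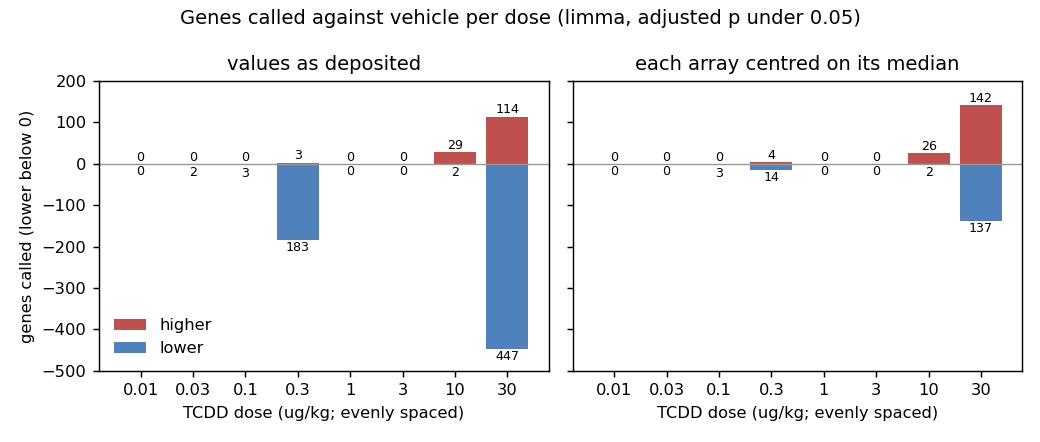
Bars give the number of genes called against vehicle at each dose, higher above 0 and lower below 0, with the deposited values on the left and each array centred on its median on the right. At 30 µg/kg, the 114 higher and 447 lower genes become 142 and 137 after centring, and the 183 lower genes at 0.3 µg/kg become 14.

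The AHR battery rose as a list at 30 µg/kg (camera adjusted p 4.4e-07, with estimated correlation 0.0034). Its direction is not an independent result, since the sign of the ratios was read from TCDD-induced genes. Cyp1a1, Tiparp (adjusted p 0.000118), Cyp2s1 (0.63 ± 0.17, adjusted p 0.0011) and Ahr (0.80 ± 0.27, adjusted p 0.0017) were called, 4 of 9 listed genes with values, and 4 when adjusted over the list alone. Nqo1 (0.15 ± 0.66), Gsta1 (0.12 ± 0.23), Nfe2l2 (-0.01 ± 0.20) and Arnt (-0.08 ± 0.03) were not called. Ugt1a6b, the remaining member, has only the value shared with other probes and was not measured. Ahrr, Cyp1a2 and Cyp1b1 lack a probe with values on all 48 arrays. In a fit of probes complete at 30 µg/kg they rose by 3.01 ± 0.66 (adjusted p 4.3e-07), 2.05 ± 0.68 (adjusted p 0.0039) and 1.80 ± 0.19 (adjusted p 0.000162).

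**Figure D2:**
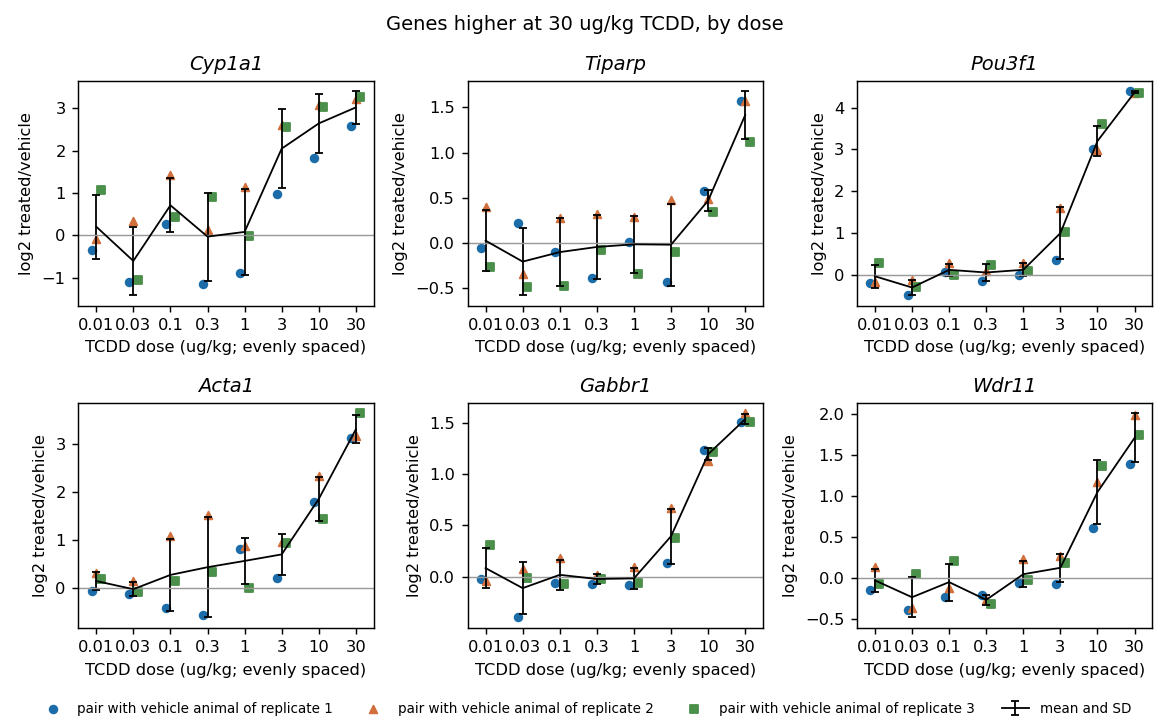
Points give the log2 ratio of treated over vehicle in each animal pair at each dose for 6 genes, with the mean and SD over 3 pairs as a line with bars. Pou3f1 and Gabbr1 are at 3.20 and 1.19 at 10 µg/kg and at 4.36 and 1.54 at 30 µg/kg, while Tiparp is at 0.47 and 1.41.

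Single genes of lipid metabolism were called at 30 µg/kg, most of them lower, as were 447 of all 561 called genes. The cholesterol uptake transporter gene Npc1l1 had a log2 ratio of -0.67 ± 0.28 (adjusted p 0.0103), with Abcg8 (-0.27 ± 0.05), Abcg5 (-0.36 ± 0.16) and Abca1 not called over all genes. In sterol transport, 1 of 10 genes was called lower, and 5 when adjusted over the list alone. The fatty acid oxidation genes Hadhb (-0.43 ± 0.25, adjusted p 0.0071) and Eci1 (-0.25 ± 0.12, adjusted p 0.0191) fell, and Acadm and Acads were not called. The long-chain acyl-CoA synthetase gene Slc27a2 fell to -0.42 ± 0.26 (adjusted p 0.0266), while Plin2 (-0.47 ± 0.40), Cd36 (0.61 ± 0.42) and Agpat3 (0.21 ± 0.48) were not called. In fatty acid synthesis, Me1 fell and Scd2 rose by 1.03 ± 0.47 (adjusted p 0.0475), and Elovl6 and Fads2 were not called. Stard4 fell to -0.49 ± 0.33 (adjusted p 0.0368) among the genes of cholesterol synthesis, where Sc5d, Hsd17b7 and Sqle were not called. No member of the bile acid list was called, with the smallest p for Cyp27a1, Cyp3a11, Slc51a and Slc51b. Centring, which moved each mean up by 0.06 (Me1 from -0.93 to -0.87, SE 0.24 in both), ended the calls of Eci1, Slc27a2, Stard4, Me1 and Scd2 (adjusted p 0.0526 to 0.0761). The block for the vehicle animal ended that of Scd2 (0.0596). Without replicate 1 only Npc1l1 stayed called (adjusted p 0.0234), but not without replicate 3 (0.111), and Scd2 was lost in each leave-out. Without both pairs with pancreas signal 1 pair is left, from which no call is drawn here. Each of the 7 kept its direction in it (Npc1l1 at -0.58, Hadhb at -0.24). That pair also entered their calls, and 558 of the 561 called genes had the same sign in all 3 pairs. The kept direction is therefore no separate support. None of these 6 lists passed camera, whose smallest adjusted p among them was 0.184, for cholesterol synthesis. The direction of that list was upward, with 12 of 18 means above 0. By fry, which does not compare a list with other genes, sterol transport (adjusted p 0.0049), fatty acid oxidation (0.0188) and fatty acid synthesis (0.0419) moved down. Fry was run without centring, so the level of the arrays can enter these shifts (median of all genes -0.05). Fabp1, Fabp2, Mogat2, Acsl5, Apoc2 and Plin3 of the fat absorption list have the shared value and were not measured.

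Single genes of retinoid metabolism and 1 named gene of conjugation were called at 30 µg/kg. Aldh1a1 fell to -0.58 ± 0.24 (adjusted p 0.0021) and Rdh7 to -0.78 ± 0.56 (adjusted p 0.0072), against the rise of Bco1, and Rarb was not called. The retinoid list moved down by fry without centring (adjusted p 0.0277) and did not pass camera (0.699), and its member Stra6 was not measured. Gstm3 had a mean of -0.71 ± 0.74 (adjusted p 0.0266) but was at 0.13 in the pair of replicate 2, the pair without pancreas signal. Gstt1, Gsta3 (-1.18 ± 0.78) and Abcc4 were not called. In the list of glutathione and NRF2 genes, 4 of 23 were lower when adjusted over the list alone, and its member Taldo1, counted among the 23, was not measured. Alas1, the first enzyme of heme synthesis, rose by 0.75 ± 0.54 (adjusted p 0.0073), and Slc46a1, Ftl1 and Ireb2 were not called. The calls of Bco1 (adjusted p 0.201), Gstm3 (0.293) and Alas1 (0.123) ended without replicate 1, and that of Rdh7 without replicate 2 (0.0795). Those of Bco1 (0.0691) and Gstm3 (0.166) also ended without replicate 3, and that of Gstm3 after centring (0.0534).

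Some genes of immune cells were called lower at 30 µg/kg. Among plasma cell genes, Jchain, Tnfrsf13b (-0.40 ± 0.08, adjusted p 0.0080) and Mzb1 (-0.30 ± 0.11, adjusted p 0.0382) fell, 3 of 10 and 4 when adjusted over the list alone, and Derl3 was not called. The T cell genes Thy1 (-0.67 ± 0.16, adjusted p 0.0014), Lat (-0.31 ± 0.21, adjusted p 0.0262) and Cd160 (-0.30 ± 0.10, adjusted p 0.0391) fell, and Tbx21 did not pass. These were 3 of 25 genes, and 4 were lower when adjusted over the list alone. Over the whole list 13 of 25 means were above 0, with a median of 0.0006 against -0.05 for all genes. Adgre1 (-0.52 ± 0.18, adjusted p 0.0256) and Itgax (-0.20 ± 0.09, adjusted p 0.0487) fell among 19 macrophage and dendritic cell genes, of which 7 were lower when adjusted over the list alone; Cybb and C1qc were not called. The mast cell protease gene Mcpt4 fell to -0.35 ± 0.26 (adjusted p 0.0292), while Ccr3, Tpsb2 and Kit were not called. Cxcr6 fell to -0.43 ± 0.23 (adjusted p 0.0305), and Id2, Lta and Il17f were not called. No B cell gene passed, although Ltb (-0.95 ± 0.36) and Tnfrsf13c (-1.05 ± 0.79) had low means. Cr2 (0.14 ± 0.08) and Cd37 (-0.15 ± 0.15) were not called either. Centring ended the calls of Lat, Cd160, Mzb1, Adgre1, Itgax, Mcpt4 and Cxcr6 (adjusted p 0.0718 to 0.195) with the same small shift (Adgre1 from -0.52 to -0.46, SE 0.13 in both). The block ended that of Mzb1 (0.0504). Without both pairs with pancreas signal 1 pair is left, from which no call is drawn here. All of these 10 genes were below 0 in it (Thy1 at -0.50, Tnfrsf13b at -0.48, Itgax at -0.10). That pair also entered their calls, and 558 of the 561 called genes had the same sign in all 3 pairs. The shared direction is therefore no separate support.

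The MHC class II list was lower as a list at 30 µg/kg by camera at its preset correlation (adjusted p 0.0042), but not with an estimated correlation (0.437). Ctss (-0.27 ± 0.23) and Ciita (-0.50 ± 0.28) were called, each at adjusted p 0.0498, and 8 of 10 genes were lower when adjusted over the list alone. H2-Eb1 (-0.55 ± 0.59) and H2-DMb1 (-0.61 ± 0.73) were not called over all genes. The list's medians in the 3 pairs were -0.90, 0.06 and -0.52, the low ones in the pairs with pancreas signal. Low medians also occurred at doses where no pair carries that signal. They were -0.20, -0.31 and -0.46 at 10 µg/kg, -0.02, 0.12 and -0.16 at 3 µg/kg, and -0.17, -0.56 and 0.23 at 0.01 µg/kg. At 30 µg/kg the camera adjusted p without replicate 1 was 0.286. Without both pairs with pancreas signal 1 pair is left there, with the median of 0.06. The MHC class I genes Psmb8, Tap2, H2-K1 and Tap1 and the interferon-response genes Iigp1, Ifit3, Irf9 and Gbp3 were not called. Of 11 class I genes, H2-D1, H2-Q7 and H2-T23 were not measured, nor were some probes of H2-K1. Saa1 (-0.25 ± 0.08, adjusted p 0.0278) and Slpi (-0.74 ± 0.25, adjusted p 0.0482) fell among the defence genes, and Ang4 and Pigr were not called. On the arrays with the treated animal in Cy3 alone, Saa1 was at 0.039. After centring, Ctss, Ciita, Saa1 and Slpi were not called (adjusted p 0.0955 to 0.158), with Slpi at -0.69 and Ciita at -0.44. Reg3b and Reg3g were not measured. By fry without centring, the plasma cell (adjusted p 0.0069), MHC class II (0.0074), innate lymphoid (0.0188) and macrophage lists (0.0310) moved down. The innate lymphoid list moved up by fry at 1 µg/kg (adjusted p 0.0445), where the median of all genes was 0.06. No immune list but MHC class II passed camera at 30 µg/kg.

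**Figure D3:**
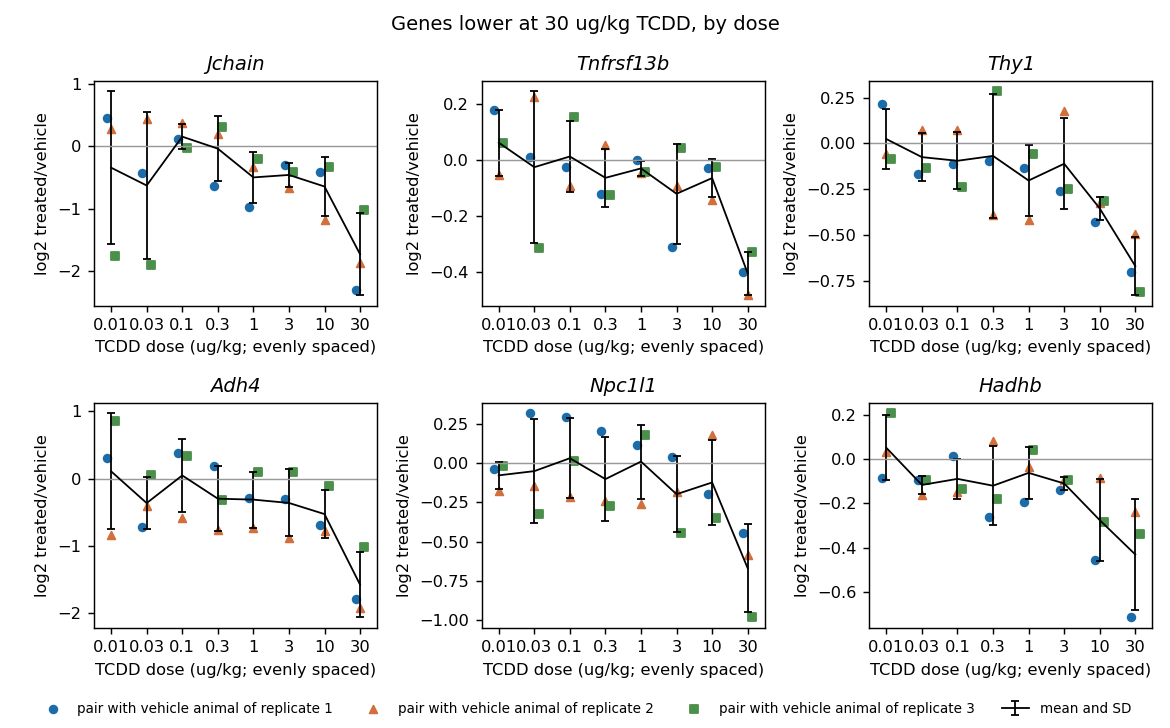
Points give the log2 ratio of treated over vehicle in each animal pair at each dose for 6 genes lower at 30 µg/kg, with the mean and SD over 3 pairs as a line with bars. Means at 30 µg/kg are -1.74 for Jchain, -1.58 for Adh4, -0.67 for Thy1 and Npc1l1, -0.43 for Hadhb and -0.40 for Tnfrsf13b.

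Among epithelial genes at 30 µg/kg, the enteroendocrine gene Chgb rose by 0.38 ± 0.27 (adjusted p 0.0105), and Sct, Sst and Pax6 were not called. The call of Chgb ended without replicate 1 (adjusted p 0.0646) or replicate 3 (0.137), the pairs with pancreas signal. It stayed without replicate 2 (0.0027), so it depends on those pairs. The Paneth cell genes Nupr1, Mptx1, Lyz1 and Mmp7 were not called, and the list's medians in the 3 pairs were -0.07, -0.06 and 1.09. No gene of the brush border list passed (smallest p for Treh, Mme, Khk and Dpp4), and Sis, Lct, Anpep and Vil1 were not measured. Nor was a goblet cell gene called (Creb3l1, Agr2, Ccl6 and Ern2 first), with Tff3, Clca1 and Zg16 not measured. Stem cell genes (Znrf3, Ephb3, Cd44 and Sox9 first) and proliferation genes (Mcm2, Ccna2, Mcm5 and Mcm4 first) were not called, and the stem cell list's member Msi1 was not measured. The proliferation list passed camera upward (adjusted p 0.0228), with pair medians of -0.19, -0.01 and 0.43, and did not pass without replicate 3 (adjusted p 0.814) or with an estimated correlation (0.680).

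Genes of other tissues were also compared. The exocrine pancreas list was higher at 30 µg/kg (camera adjusted p 1.1e-08, with estimated correlation 0.437). Ctrl (0.56 ± 0.48, adjusted p 0.0498) was called, though not with the block (0.0575) or after centring (0.0534). Prss2 (1.85 ± 1.80), Cela1 (1.34 ± 1.48) and Cpa1 (1.71 ± 1.84) were not called. The medians of this list in the 3 pairs were 2.83, -0.06 and 0.60. Without replicate 1, its camera adjusted p was 0.0440. Of the stroma genes, Thy1 was the only one called, ahead of Pdgfra, Col1a1 and Mylk. The endothelial genes Flt1, Cdh5, Kdr and Lyve1 were not called, though the list moved down by fry without centring (adjusted p 0.0049). Neither adipose (Cd36, Pparg, Lep and Acvr1c first), clock (Clock, Nr1d1, Dbp and Per2) nor stress-response genes (Hsp90b1, Asns, Atf4 and Sesn2) were called. The erythrocyte genes Slc4a1 (-0.09 ± 0.15) and Hba-a1 (0.02 ± 0.17) were too few for a list test.

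**Figure D4:**
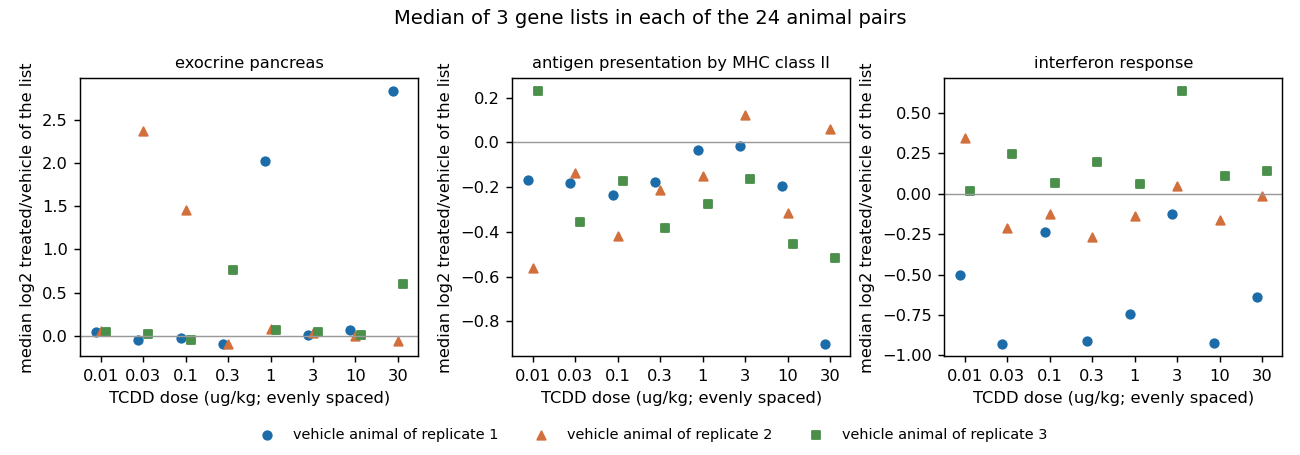
Points give the median log2 ratio of treated over vehicle over the genes of 3 lists in each animal pair at each dose, marked by vehicle animal. The pancreas list reaches 2.83 in 1 pair at 30 µg/kg and 2.38 in 1 pair at 0.03 µg/kg, and the interferon list is at -0.93 to -0.13 in all pairs with the vehicle animal of replicate 1.

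At 10 µg/kg, 31 genes were called, 29 higher and 2 lower. The largest rises were those of Pou3f1 (3.20 ± 0.36, adjusted p 3.2e-10), Cyp1a1 (2.64 ± 0.70, adjusted p 0.0057) and Acta1 (1.86 ± 0.45, adjusted p 0.0045). Gabbr1 (1.19 ± 0.06), Wdr11 (1.05 ± 0.39), Rab33a (0.68 ± 0.17) and Olfr1182 (0.41 ± 0.13) also rose. Hspa14 (-0.46 ± 0.26, adjusted p 0.0293) and Txnrd3 (-0.39 ± 0.11, adjusted p 0.0415) fell. Tiparp (0.47 ± 0.12) and Ahr (0.58 ± 0.28) were not called at this dose. Of the 29 genes higher at 10 µg/kg, 21 were also higher at 30 µg/kg, where independent calls would share 0.253. Txnrd3 was lower at both doses. The shared vehicle animals make such calls dependent. Over all genes the means at the 2 doses correlated at 0.52. In 100 simulated data sets without change this was 0.27, which follows from the variance share set for the vehicle animals (0.269). The correlation was also 0.52 between 3 and 10 µg/kg and 0.48 between 1 and 10 µg/kg, with no gene called at 1 and 3 µg/kg. Between 0.01 and 30 µg/kg it was -0.04. A correlation of 0.52 is thus not particular to 10 and 30 µg/kg. The covariance of the means was largest for these 2 doses, at 0.0139 against 0.0040 in the simulated sets. It was 0.0071 between 3 and 10 µg/kg and 0.0081 between 1 and 10 µg/kg. A covariance also grows with the spread of the means at each dose. Leaving out 1 of the 3 pairs left 12, 15 and 12 called genes. The call of Cyp1a1 then ended without replicate 2 (adjusted p 0.100) and without replicate 3 (0.0786), that of Acta1 without replicate 1 (0.0576) and replicate 2 (0.106), that of Hspa14 without replicate 1 (0.503) and replicate 2 (0.329), and that of Txnrd3 without any one of them (0.435, 0.0960 and 0.148).

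The AHR battery was the list shifted at 10 µg/kg by camera with both correlations (adjusted p 7.1e-05, estimated 0.0212). With the preset correlation 9 more lists passed. MHC class II (median -0.32), class I, interferon, proliferation and the stress response were lower, and enteroendocrine, retinoid, stroma and adipose genes were higher. Only AHR and MHC class II passed without replicate 1, which left 2 lists. The interferon medians in the 3 pairs were -0.92, -0.16 and 0.11, and the proliferation medians -0.33, -0.62 and 0.44. Without replicate 2 the proliferation list turned upward (camera adjusted p 0.453).

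At 3 and 1 µg/kg, limma called 0 genes, with 498 and 1693 genes at an unadjusted p under 0.05. Cyp1a1 had a mean of 2.05 ± 0.92 at 3 µg/kg, above 0 in all 3 pairs, with an adjusted p of 0.788. Pou3f1 had 0.99 ± 0.62 at this dose (adjusted p 0.0714). At 0.01 µg/kg 0 genes were called, with 485 at an unadjusted p under 0.05.

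At 0.3 µg/kg, 186 genes were called, 3 higher and 183 lower, with a median absolute log2 ratio of 0.31. Taf15 fell most (-1.08 ± 0.15, adjusted p 0.00021), followed by Gprin3 (-1.04 ± 0.53, adjusted p 0.0071) and Smc2 (-0.91 ± 0.14, adjusted p 0.0071). Fut4-ps1 (0.35 ± 0.20, adjusted p 0.0468) and Fbln1 (0.26 ± 0.07, adjusted p 0.0327) rose. After array centring 18 genes were called, and 13 without replicate 3. The dye-swapped arrays of that pair correlated at 0.018 with the dye profile removed, the lowest of all pairs, and the pair carries pancreas signal (median 1.31). Taf15 stayed called without any 1 of the pairs. Gprin3 and Smc2 were not called without replicate 2 (adjusted p 0.0574 and 0.0533) or replicate 3 (0.0780 and 0.118), Fut4-ps1 without replicate 2 (0.140) or 3 (0.294), and Fbln1 without replicate 1 (0.0570), 2 (0.0792) or 3 (0.238).

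Taf15 and Dag1 were also the genes called at 0.03 µg/kg (-0.81 ± 0.13 and -0.32 ± 0.13; adjusted p 0.0272 and 0.0428). With Uggt1 (-0.43 ± 0.01, adjusted p 0.0443), they were the 3 called at 0.1 µg/kg (Taf15 -0.92 ± 0.03, adjusted p 0.0048; Dag1 -0.36 ± 0.08, adjusted p 0.0086). At both doses 0 genes were called when any 1 pair was left out. At 30 µg/kg Taf15 (-0.88 ± 0.24), Dag1 (-0.28 ± 0.10), Uggt1 (-0.28 ± 0.23), Gprin3 (-0.82 ± 0.25) and Txnrd3 (-0.53 ± 0.07) were lower, and Fut4-ps1, Fbln1, Smc2 and Hspa14 were not called. After centring, the call of Uggt1 at 30 µg/kg ended (adjusted p 0.109), and the other lower genes stayed called. From 0.01 to 3 µg/kg, camera passed 5, 3, 4, 2, 7 and 2 lists, and 0 at each of these doses with an estimated correlation. MHC class II was among the lists lower at 0.01, 0.1 and 1 µg/kg, with medians of -0.18, -0.28 and -0.13.

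A slope on log10 dose was called for 49 genes, 37 rising and 12 falling. The count was higher after array centring and with the block for the vehicle animal, as given below. Per 10-fold dose, Pou3f1 rose by 1.22 ± 0.15 (SE, adjusted p 0.000245), Cyp1a1 by 0.96 ± 0.16 (adjusted p 0.0028), Bco1 by 0.82 ± 0.16 (adjusted p 0.0126), Acta1 by 0.79 ± 0.12 (adjusted p 0.0019) and Wdr11 by 0.46 ± 0.08 (adjusted p 0.0019). The steepest falling slopes were those of Gstm3 (-0.30, adjusted p 0.0019), Cyp3a25 (-0.27, adjusted p 0.0183), Rnf130 (-0.18, adjusted p 0.0249), St6gal1 (-0.17, adjusted p 0.0355) and Cat, the catalase gene (-0.17, adjusted p 0.0437). The means of these genes at 30 µg/kg were -0.71 ± 0.74, -0.81 ± 0.18, -0.56 ± 0.01, -0.76 ± 0.22 and -0.50 ± 0.30. Without replicates 1, 2 and 3, 16, 124 and 8 slopes were called. The slope of Pou3f1 was called each time. Those of Cyp1a1 (adjusted p 0.0575), Acta1 and Wdr11 (each 0.0502), Bco1 (0.222) and Gstm3 (0.162) were not called without replicate 3. Those of Cyp3a25 (0.126 and 0.206) and Cat (0.339 and 0.187) were not called without replicate 1 or 3, nor those of Rnf130 (0.100, 0.0703 and 0.151) and St6gal1 (0.353, 0.119 and 0.0683) without any one of them.

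Between 30 and 10 µg/kg, 4 genes differed in the fit without a block for the vehicle animal. More genes differed with the block, as counted below. Olfr114 (difference 1.36 ± 0.17 SE, adjusted p 0.0025), Rab33a (0.54 ± 0.08, adjusted p 0.0129) and Olfr1182 (0.53 ± 0.09, adjusted p 0.0369) were higher at 30 µg/kg, and Dnase1 (-1.03 ± 0.15, adjusted p 0.0062) was lower. The difference for Cyp1a1 was 0.38 ± 0.60 (adjusted p 0.966) and that for Pou3f1 1.16 ± 0.23 (adjusted p 0.105). Leaving out replicates 1, 2 and 3 left 0, 0 and 1 called genes, the last being Olfr114 (adjusted p 3.9e-06).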

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

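The tests of vehicle animals below, the probes outside the gene tests and the alternatives with pancreas signal were chosen after the results were seen.

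Genes whose change differed between 30 and 10 µg/kg were Dnase1 (-1.03), Olfr114 (1.36), Olfr1182 (0.53) and Rab33a (0.54), by a test of the difference without the block. Data outside the gene tests also held changes at 30 µg/kg. Of 1695 genes with values on all arrays at 30 µg/kg but not on all 48, 37 were called there, 16 higher and 21 lower. They were led, among others, by Ahrr (3.01), Apobec2 (2.78), Cyp1a2 (2.05) and Cyp1b1 (1.80), and the falls included those of Prss23 (-0.95) and Tnfrsf17 (-0.70), named after their values were seen. Among 3269 complete probes that name no single gene, 30 were called at 30 µg/kg, 6 higher and 24 lower, against 0 at 0.01, 1 and 3 µg/kg and 60 at 0.3 µg/kg.

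Of the 186 genes called at 0.3 µg/kg, 183 were lower. An offset of the arrays may account for most of these calls. The median of all genes was below 0 in all 3 pairs (-0.08, -0.08 and -0.09), and after centring 18 genes were called, with the median of the 186 moving from -0.31 to -0.22 at a standard error of 0.06 in both. Centring shifts all genes at a dose by the same amount, which was small beside the values of the called genes. That all 183 stayed below 0 is therefore no separate evidence. Centring ended calls by shrinking the values and does not show that the genes were unchanged. An offset of dim spots was tested on 537 olfactory receptor genes, whose median was only -0.00042 from that of all genes. This argues against such an offset only if these spots are dimmer than most, which cannot be checked without intensities.

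The exocrine pancreas genes were higher at 30 µg/kg in 2 of 3 pairs. An effect of TCDD at this dose is argued against by the lowest pair, with a median of -0.0051 over 10 enzyme genes. Pancreas tissue carried over with the jejunum of some treated animals may be the source, as the enzyme genes kept together over the 24 pairs with a mean pairwise correlation of 0.812 and a lowest one of 0.369. In 6 pairs their median was at least 1.08, 4 of them at doses under 30 µg/kg and 2 with each vehicle animal, against at most 0.13 in the other 18. Without the 2 such pairs at 30 µg/kg, 71 genes were called, from a lone pair assumed to vary like the other groups, and with the signal as a covariate 161.

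Taf15, Dag1 and Uggt1 were lower at 0.03, 0.1, 0.3 and 30 µg/kg in 12 of 12 pairs each, with a mean of -0.57. Their mean was -0.04 at 1, 3 and 10 µg/kg and -0.11 at 0.01 µg/kg. The genes and doses were picked for this pattern, so the sign shared by the pairs is largely given by that choice. Taf15 was at 0.36, -0.14 and -0.18 at 1, 3 and 10 µg/kg, with 1 pair at 3 µg/kg at -0.52, close to the highest of its pairs at the doses where it was lower (-0.62). Uggt1 had a mean of -0.13 over these 3 doses and was as low at 10 µg/kg (-0.30) as at 30 µg/kg (-0.28), so it follows the pattern only in part. Array offsets are argued against, since the mean was -0.516 after centring, although centring ended the call of Uggt1 at 30 µg/kg. Each vehicle animal is set against all doses, so it alone would lower the genes alike at every dose. Within vehicle animals the doses differed by 0.528 with a standard error of 0.05 in these 3 genes, which were chosen for that difference. A difference among the 8 doses, tested with a term per vehicle animal and adjusted over all genes, was called for Taf15 (adjusted p 0.000232), Dag1 (0.0011) and Uggt1 (0.0101), among 211 genes, which argues against the vehicle animals alone. Doses handled as separate batches cannot be told apart from an effect that does not follow dose, as the labels give no batch and each dose is 1 group. A departure from a straight line in log10 dose was found for 16 genes, 0.122% of those tested.

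Whether chance groupings give as many calls was asked by turning the signs of pairs within a dose, which allows only 4 patterns and so no share under 0.05. At 30 µg/kg the real signs gave 561 genes and the highest other pattern 2, with 1 pattern as high as the real one. At 0.3 µg/kg these were 186, 4 and 1, at 0.1 µg/kg 3, 0 and 1, and at 0.03 µg/kg 2, 0 and 1. At 10 µg/kg 31 genes stood against 78 in another pattern, with 2 patterns as high. At 0.01, 1 and 3 µg/kg all 4 patterns gave 0. For lists from 0.01 to 30 µg/kg, the real counts were 5, 3, 4, 2, 7, 2, 10 and 4, the highest others 11, 9, 6, 3, 5, 4, 5 and 10, and the patterns as high 4, 4, 2, 3, 1, 3, 1 and 3.

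For the 4 genes differing between 30 and 10 µg/kg, 3 of the 10 splits of the 6 pairs gave as many, too few splits for a share under 0.05. The highest other gave 785. The 4 splits that exchange doses within vehicle animals gave at most 0 besides the real one. The split with 785 is thus among those that keep both pairs of a vehicle animal on the same side. Such a split also compares vehicle animals. With dose means removed, ratios with the same vehicle animal correlated with a mean of 0.28, and those with different ones with -0.14. The 785 genes may therefore reflect the shared vehicle animals, which was not tested further. For the slope, 2 of 100 assignments of the doses within vehicle animals, the real one included, gave at least 49 genes. This share is under 0.05, so a count this high is unlikely by chance but not excluded. The share says nothing about single slopes. The other of the 2 assignments gave 175 genes, and 98 gave 0.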

How the results depend on the processing

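The alternatives with complete probes per dose, pancreas signal and the shared value were chosen after seeing the data; the others were fixed before. The counts as reported were 0, 2, 3, 186, 0, 0, 31 and 561 genes from 0.01 to 30 µg/kg, 49 slopes, 4 differences between 30 and 10 µg/kg, and 5, 3, 4, 2, 7, 2, 10 and 4 lists. Unless a value is named, a count stayed within 1.5 times, and the cause of a move was not tested.

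A replicate block for the vehicle animal gave 1 gene at 0.03 µg/kg, 5 at 0.1 µg/kg, 185 at 0.3 µg/kg, 40 at 10 µg/kg and 621 at 30 µg/kg, 103 slopes and 12 differences; 533 of the 621 were among the 561. With the block the lists numbered 6, 3, 4, 2, 7, 2, 10 and 4.

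Arrays of a single dye orientation are not averaged over a dye swap. With the treated animal in Cy5 only, the counts were 119, 443, 429, 1666, 656, 439, 630 and 1842 genes, 31 slopes and 2 differences. With Cy3 only, they were 94, 498, 649, 1862, 88, 304, 362 and 1061 genes, 32 slopes and 1 difference.

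Centring each array gave 0 genes at 0.03 µg/kg, 18 at 0.3 µg/kg, 279 at 30 µg/kg, 82 slopes and 1 list each at 0.3 and 3 µg/kg. Quantile normalization gave 0 at 0.03 µg/kg, 3 at 0.3 µg/kg, 109 at 30 µg/kg and 0 differences. Array weights gave 783 genes at 0.03 µg/kg, 10 at 0.1, 47 at 0.3, 269 at 1, 1 at 3, 14 at 10 and 155 at 30 µg/kg, and 2 differences. The pairs of a dose alone, with 2 residual degrees of freedom, gave 0 genes at 0.03 and 0.3 µg/kg, 1 at 0.1 and 10 µg/kg and 4 at 30 µg/kg.

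At least 1.5-fold changes were called for 1, 1, 17, 10 and 102 genes at 0.03, 0.1, 0.3, 10 and 30 µg/kg, with 30 slopes (over the whole dose range) and 2 differences. At adjusted p under 0.01 there were 0, 24, 17 and 137 genes at 0.03, 0.3, 10 and 30 µg/kg, 20 slopes and 2 differences; both follow from stricter thresholds. Probes complete at the dose gave 0 genes at 0.03 µg/kg. The pancreas signal as a covariate gave 0 genes at 0.03 µg/kg and 161 at 30 µg/kg. Without the pairs with this signal there were 0, 0, 13 and 71 genes at 0.03, 0.1, 0.3 and 30 µg/kg, and 0 and 1 lists at 0.03 and 0.1 µg/kg. Without the probes at the shared value, 174, 31 and 545 genes were called at 0.3, 10 and 30 µg/kg, 50 slopes and 4 differences.

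Leaving out each pair in turn gave 0 genes at 0.03 and 0.1 µg/kg, 13 to 138 at 0.3 µg/kg, 0 to 1 at 3 µg/kg, 12 to 15 at 10 µg/kg and 175 to 404 at 30 µg/kg. Leaving out each replicate gave 8 to 124 slopes and 0 to 1 differences. Lists numbered 6 to 8, 0 to 6, 1 to 7, 1 to 6, 5 to 9, 1 to 3, 2 to 11 and 3 to 9 from 0.01 to 30 µg/kg. An estimated correlation left 0 lists at each dose up to 3 µg/kg and 1 at 10 and at 30 µg/kg, the AHR battery. By fry there were 0 lists at 0.01, 0.03, 0.1 and 3 µg/kg, 5 at 0.3, 4 at 1, 1 at 10 and 10 at 30 µg/kg. Fry was not run after centring. Its lists were all lower at 0.3 µg/kg and all higher at 1 µg/kg, where the medians of all genes were -0.08 and 0.06.

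Of the alternatives for named genes, 1991 kept direction and call, 432 lost and 52 gained the call, and 3 reversed. Gabbr1 at 30 µg/kg was at -0.023 by its weakest probe, Gstm3 at 0.13 without the pairs with pancreas signal, and Saa1 at 0.039 with Cy3 only. For single lists 88 kept direction and call and 41 lost the call, and proliferation at 10 µg/kg turned upward without replicate 2 (adjusted p 0.453, against 5.3e-14 without replicate 3). The files hold no signal over background, so what dim spots limit is unknown.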

Other observations

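The interferon-response list was lower in all 8 pairs with the vehicle animal of replicate 1, with medians of -0.93 to -0.13 from 0.01 to 30 µg/kg. With the other vehicle animals its medians lay between -0.27 and 0.64. The medians with the vehicle animal of replicate 1 did not follow dose, with -0.50 at 0.01, -0.13 at 3 and -0.64 at 30 µg/kg. These values argue against TCDD as the source of the falls in these 8 pairs. The vehicle animal that the pairs share was not tested further as a source.

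Probes at the value shared by 203 to 335 probes on an array include abundant transcripts of the gut such as Fabp1, Fabp2, Lct and Anpep, and also Olfr571 and Opn5. The files hold no intensities or spot quality marks, so their origin was not tested.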
